A study of Mus musculus with 8 samples.

How the data were processed

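RNA of GFP-positive cells, sorted from dissected kidney rudiments of mouse embryos of the NMRI strain at stage E11.5, was measured on 8 arrays of 1 colour. Per the labels, each sample was a pool of about 100000 cells of both sexes from several rounds of sorting, and 20 ng of total RNA was amplified and labelled with a fluorescent dye, or 10 ng for replicate 3 of control and null. The labels gave every group and replicate number: 3 controls, 3 Tbx18 nulls and 2 Tbx18VP16 samples.

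The scanner files hold spot intensity values that Agilent Feature Extraction 10.7.3.1 had already corrected for background, per the file headers, together with flags for outlier spots, saturation and signal well above background. The authors' deposited value table holds intensity on a linear scale. Its 8 columns have identical sorted values, a lowest value of 10 reached by 11190 probes and a median of 93.77 in every column, so it was quantile-normalised across all arrays with a floor, while the software used is not given in the sources used here. It served as an alternative.

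Control and null arrays were of 1 array design and Tbx18VP16 arrays of another. The 39429 probes of 60 bases named on both were used, each with 4 spots per array. Control spots and outlier spots (1.86% to 2.55%) were left out, spots of a probe were averaged, and log2 of the processed signal minus the array's 75th percentile over these probes was taken. The 75th percentile of the processed signal was between 975 and 2127. Through RefSeq gene tables of assembly GRCm38.p6, 28781 probes were named by accession, 3388 by symbol and 247 by synonym, 4682 kept the name in the files and 2331 had none. Of the accessions, 42 pointed to different genes in the files of the 2 designs. Coordinates are those of the files (mm9).

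A probe was tested if well above background on at least 3 of the 6 control and null arrays, or on at least 2 of all 8, and each gene was represented by its probe of highest mean level. Null and control were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on their 6 arrays. Tbx18VP16 was compared with control and with null in a limma fit of 3 group means on all 8 arrays, which pools the spread of groups because a group of 2 gives little of its own. Adjusted p values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and tests are two-sided. Gene lists were tested with limma's camera at its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 35 lists of at least 3 tested genes. Of the null calls, that of the extracellular matrix list also held with an estimated correlation. That form of camera also tests on the residual degrees of freedom of the fit: 4 for null, 5 for Tbx18VP16 and 2 for the blocked null fit. Its larger p values thus need not come from correlation between genes. For the extracellular matrix list in the null, the estimated correlation was -0.024, below the preset 0.01. A camera test compares a list with the other genes. For a probe well above background on no array of a group, a fold is a lower bound: the mean of the brighter group over the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

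The designs, the lists, the alternatives of normalisation, background, filter, replicate and block, and the rule for named genes were fixed before the data were examined. The rule took Tbx18, the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between groups, or where fewer than 5 passed in a direction up to 8 genes of smallest p with at least a 2-fold change. It added up to 4 members of smallest p from each described list and the 6 largest shared changes per direction, and left out probes with clone-like or predicted names. Some genes that the rule takes are not reported here. Replicate numbers were checked as pairs. Deviations from the group means correlated across genes at 0.829, 0.707 and 0.432 for control and null samples of the same number. Samples of different number gave -0.754 to 0.324, the highest for control 3 and null 2. The numbers thus paired pools 1 and 2 clearly and pools 3 less so. Levels of control 3 correlated at 0.970 with null 3 but at 0.983 with control 2. Fits with the number as a block (limma) stand beside the others for null against control. That block leaves 2 residual degrees of freedom.

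The fits were tested on simulated data with 50 genes changed at each fold. For null against control without the block, 1, 32, 45 and 49 of 50 genes were called at 2, 4, 8 and 16-fold among 19513 genes. With the block, 35, 50, 49 and 50 were called, with 21 unchanged genes called as well. For Tbx18VP16 against control 3, 33, 46 and 49 were called, with 12 unchanged genes called, among 20388 genes, and for Tbx18VP16 against null 1, 30, 48 and 49, with 5. Both Tbx18VP16 comparisons were simulated with independent arrays, without the deviations that same-numbered control and null pools shared. Each comparison was simulated in 1 data set. There, unchanged genes made up more of the calls than the threshold of 0.05 aims at, in the blocked fit and in Tbx18VP16 against control. The threshold holds on average over repeats, so 1 run does not measure an excess. Chance overlap of the calls against shared controls was simulated 100 times. Tables and figures were made with the R package data.table, version 1.17.8, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

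Correlations between arrays were taken over the 20388 genes tested in the fit of all 8 arrays. They were 0.957 to 0.995 within groups, 0.956 to 0.993 between control and null, and 0.953 to 0.969 between Tbx18VP16 and the others. Probes were called rich in A if any window of 15 bases held at least 11 A, a rule set after the data were seen.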

Results

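The series profiled GFP-positive cells sorted from mouse kidney rudiments at stage E11.5, when the ureteric bud has entered the metanephric mesenchyme. Tbx18 encodes a T-box transcription factor of the mesenchyme that surrounds the early ureter. The 3 control arrays carried RNA from embryos heterozygous for a GFP allele of Tbx18, and the 3 Tbx18 null arrays from embryos homozygous for it. The 2 Tbx18VP16 arrays carried RNA from embryos heterozygous for a Cre allele of Tbx18. This Tbx18-driven Cre activated a fusion of Tbx18 to the VP16 activation domain, together with GFP, from the Hprt locus. Their comparison with control thus also sets a Cre allele of Tbx18 against a GFP allele. VP16 turns a DNA-binding protein into an activator, so the design asks which transcripts follow the loss of Tbx18 and which follow its activating form. Each array held a pool of about 100000 sorted cells of both sexes. Between 60.1% and 66.0% of the 39429 probes present on every array were well above background, and no spot was saturated. Replicates were separate pools, so p-values without the block measure the spread between pools, and those with the block the spread of differences within pairs. For Tbx18VP16 the spread was pooled over the 3 groups, and the fit took all arrays as independent. The small number of arrays limits the precision. Levels are log2 signals relative to each array's 75th percentile, and changes are given in log2 with the standard error of the fit.

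Tbx18 itself came first among the values compared, as a check of the labels. Its probe lies on the minus strand of chromosome 9, from 87599514 to 87599573 in the mm9 build, and starts at base 2740 of the transcript that the probe was designed on. The level was 0.74 ± 0.66 (SD, n = 3) in control, -2.04 ± 0.60 (SD, n = 3) in Tbx18 null and 1.20 ± 0.20 (SD, n = 2) in Tbx18VP16 pools. The change in Tbx18 null pools was -2.77 ± 0.44 (SE), with an adjusted p of 0.12 without and 0.031 with the replicate number as a block. In Tbx18VP16 pools the change was 0.46 ± 0.46 (SE; adjusted p = 0.583). The labels state neither which part of Tbx18 the GFP allele removes nor whether the transgene carries the region of this probe, so the probe is a limited check. No probe for GFP, Cre or VP16 was found under those names.

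In Tbx18 null pools, genes of nephron progenitors stood higher and genes of the extracellular matrix stood lower than in controls as lists (adjusted p = 0.0555 and 0.0413 with an estimated correlation, and 0.572 each with the replicate block as well). Wt1 and Six2, transcription factors of the nephron progenitor state, were at 3.49 and 2.91 in the null against 1.84 and 0.39 in control pools. Fbln5, which helps assemble elastic fibres, and the proteoglycan genes Lum and Dcn had changes of -3.66 ± 0.43, -2.75 ± 0.56 and -1.50 ± 0.32 (SE, n = 3 and 3). No single gene passed the test over all 19513 genes without the pairing of pools in the fit of the 6 arrays, where the smallest adjusted p was 0.0527. With the replicate number as a block, 175 genes changed (15, 0 and 1036 without pair 1, 2 and 3), of which 91 rose and 84 fell, and 173 of them changed at least 2-fold. In 1 data set simulated for this comparison the blocked fit also called 21 unchanged genes, more than its threshold aims at.

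**Figure D1:**
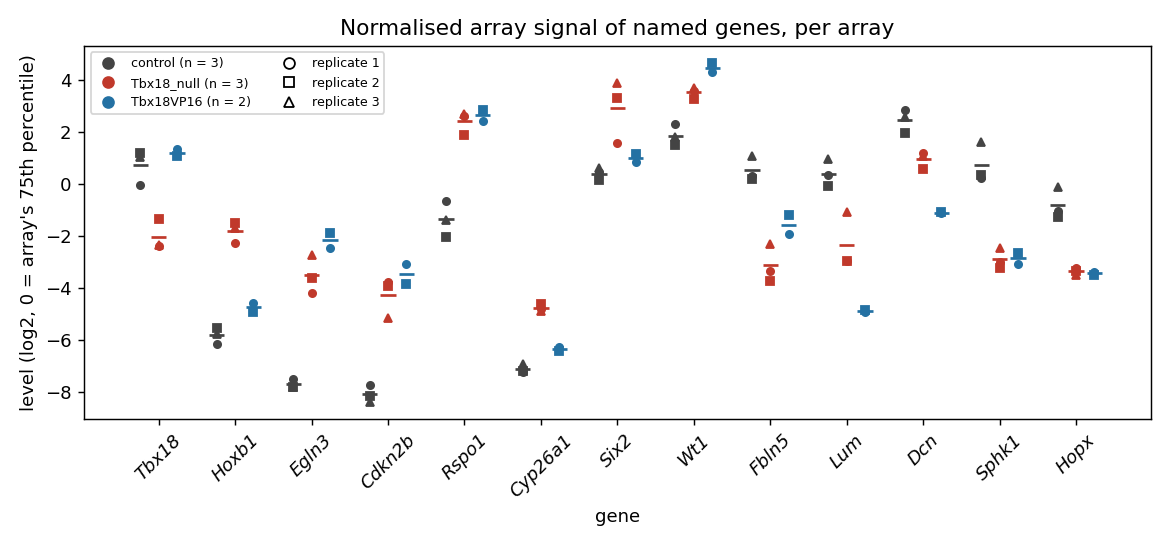
Level of named genes on each array, in log2 relative to the array's 75th percentile, with colour for the group, symbols for the replicate number and short lines for group means. Tbx18 lay at -2.04 in the null against 0.74 in control pools, and Hoxb1 at -1.82 against -5.82.

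Of the genes nearest the threshold, 8 were higher in the null. Hoxb1, a homeobox gene at the anterior end of the Hoxb cluster, had the smallest p, with a change of 4.0 ± 0.30 (SE; adjusted p = 0.0527, blocked 0.0149), and was well above background on 2 of the 3 control arrays. Another 3 genes were well above background on no control array, so their changes are lower bounds. Egln3, a prolyl hydroxylase of the oxygen-sensing pathway, was at least 10.6-fold higher (adjusted p = 0.0642, blocked 0.031). Cdkn2b, which encodes an inhibitor of cyclin-dependent kinases, was at least 6.20-fold higher (adjusted p = 0.0721, blocked 0.0215). Cyp26a1, an enzyme that degrades retinoic acid, was at least 4.21-fold higher (adjusted p = 0.0642, blocked 0.0215). Rspo1, which encodes a secreted enhancer of WNT signalling, had a change of 3.76 ± 0.42 (SE; adjusted p = 0.0721, blocked 0.0179). Ccdc160, Lhx3 and Sqor had changes of 2.69, 2.51 and 2.35, with blocked adjusted p of 0.0284, 0.0179 and 0.0179. Lhx3 was well above background on 1 of the 3 control arrays.

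The 8 genes nearest the threshold with lower levels included Fbln5, with an adjusted p of 0.0721 and 0.015 with the block. Sphk1, a sphingosine kinase, had a change of -3.64 ± 0.43 (SE; adjusted p = 0.0721, blocked 0.0179). Sntg1, a syntrophin gene, had a change of -2.73 and was well above background on 1 of the 3 null arrays. Hopx, an atypical homeodomain gene, and Asb18 had changes of -2.56 and -2.04. Otor, Sstr1 and Ptn, of which the last encodes the heparin-binding growth factor pleiotrophin, had changes of -2.0, -1.89 and -1.79. Blocked adjusted p of these 8 genes lay between 0.015 and 0.0454, and none passed without the block in the fit of the 6 arrays, whereas Sphk1, Sntg1, Hopx and Sstr1 passed in the fit of all 8 (adjusted p = 0.023, 0.0227, 0.0261 and 0.0227).

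As a group, the 18 measured nephron progenitor genes rose relative to other genes in the null (camera adjusted p = 4.90e-12, and adjusted p = 0.0555 with an estimated correlation). Of these, 15 were higher, 9 passed when adjusted over the list alone, and 0 passed over all genes, or 3 with the block. Meox1, a homeobox gene, had a change of 3.1 ± 0.62 (SE; blocked adjusted p = 0.0272), and Fgf20, a growth factor of these cells, one of 3.41 ± 0.73 (SE; blocked 0.0436). Fgf20 was well above background on 1 of the 3 control arrays. Wt1 had a change of 1.65 ± 0.28 (SE; blocked 0.0408) and Six2 one of 2.52 ± 0.57 (SE; blocked 0.105). The list's median change was 0.67, 1.11 and 1.14 in replicate pairs 1, 2 and 3.

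The 22 measured extracellular matrix genes fell relative to other genes (camera adjusted p = 2.36e-12, and adjusted p = 0.0413 with an estimated correlation). Of these, 19 were lower, 6 passed when adjusted over the list alone, and 0 passed over all genes, or 4 with the block. Fbln5, Dcn and Lum had blocked adjusted p of 0.015, 0.031 and 0.0406, while Col3a1, a fibrillar collagen gene, had a change of -0.88 ± 0.25 (SE; blocked 0.0669). The median change of the list was -0.54, -0.67 and -0.995 in the 3 pairs. With both the block and an estimated correlation, neither this list nor that of nephron progenitors passed (adjusted p = 0.572 for each). That test has 2 residual degrees of freedom and so little power.

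Renal stroma genes fell as a list of 17 (camera adjusted p = 0.00238, and adjusted p = 0.173 with an estimated correlation), but the members moved both ways. Adjusted over the list alone, 3 were lower and 2 higher. Dcn and Sfrp1, which encodes a secreted WNT antagonist, had changes of -1.50 and -0.80, whereas Smoc2 and the guidance cue Ntn1 had changes of 1.42 and 1.30. Smooth muscle genes fell as a list of 9 (camera adjusted p = 0.0488, and adjusted p = 0.289 with an estimated correlation; lost in 11 of 16 alternatives), with 7 members lower. All 13 measured cartilage genes were lower (camera adjusted p = 0.000125, and adjusted p = 0.14 with an estimated correlation). Of 19 genes of the BMP and TGF-beta pathway, 14 were lower (camera adjusted p = 0.0367, and adjusted p = 0.289 with an estimated correlation; lost in 9 of 16 alternatives). The median change of this list was -0.063, -0.066 and -0.575 in pairs 1, 2 and 3, so the fall lay mostly in pair 3. Bmp5, a BMP ligand gene, had a change of -1.58 ± 0.25 (SE; blocked adjusted p = 0.0302). Adjusted over each list alone, 1 gene of the BMP list was lower and 0 of the smooth muscle and cartilage lists.

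Hypoxia and glycolysis genes rose as a list of 18, with 15 members higher and 1, Egln3, passing when adjusted over the list alone (camera adjusted p = 1.74e-05, and adjusted p = 0.173 with an estimated correlation). The 15 genes of FGF signalling and its feedback rose (camera adjusted p = 0.0384, and adjusted p = 0.289 with an estimated correlation), a call that was lost with the block (adjusted p = 0.117) and in 11 of 16 alternatives in all. The median change of this list was -0.187, 0.114 and 0.352 in pairs 1, 2 and 3, and 6 members were higher in pair 1. Adjusted over the list alone, 3 were higher and 1 was lower. With the block, 2 members passed as higher and 1 as lower over all genes. Etv4, a transcription factor induced by FGF signalling, had a change of 2.48 ± 0.33 (SE; blocked adjusted p = 0.031). The ligand genes Fgf9, Fgf10 and Fgf7 had changes of 2.93, 1.25 and -1.49, and Fgf9 was well above background on 1 of the 3 control arrays.

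Markers of other cell types also stood higher in the null pools. Genes of erythroid cells rose as a list of 14 (camera adjusted p = 0.000423, and adjusted p = 0.466 with an estimated correlation). So did 13 of endothelium (adjusted p = 3.74e-06, and adjusted p = 0.38 with an estimated correlation), and 19 of ureteric epithelium (adjusted p = 5.29e-08, and adjusted p = 0.369 with an estimated correlation). White blood cell genes, 8 in number, rose too (adjusted p = 0.0178, and adjusted p = 0.304 with an estimated correlation), and lost the call with the block (adjusted p = 0.058). In all 4 lists, 0 members passed when adjusted over the list alone. Krt18 and Krt19, keratin genes of epithelia, had changes of 2.18 ± 0.58 and 1.53 ± 0.43 (SE), and Cldn5, a tight junction gene of endothelium, one of 2.44 ± 1.03 (SE). The 54 genes of these lists differed between pairs of pools, with median changes of 0.11, 0.77 and 3.24 in pairs 1, 2 and 3. Without null replicate 3, the endothelial, erythroid and white blood cell lists did not pass (adjusted p = 0.14, 0.998 and 0.14).

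**Figure D2:**
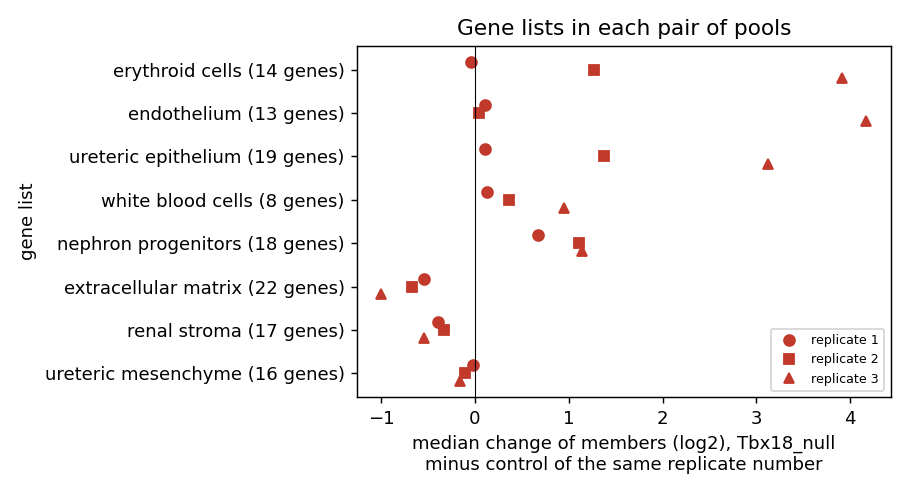
Median change of the measured members of 8 gene lists in each pair of pools, null minus control of the same replicate number, on a log2 axis, with a symbol per pair. Erythroid genes lay at -0.04, 1.27 and 3.91, whereas nephron progenitor genes lay at 0.67, 1.11 and 1.14.

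Neural crest and neuron genes rose as a list of 12 (camera adjusted p = 0.000231, and adjusted p = 0.304 with an estimated correlation), with 9 members higher and medians of 0.11, 0.92 and 1.15 in pairs 1, 2 and 3, near 0 in pair 1 like the markers of other cells. Skeletal muscle genes, 7 measured, and genes of coelomic and gonadal mesothelium, 10 measured, rose with adjusted p of 0.0439 and 0.0488 (adjusted p = 0.289 and adjusted p = 0.399 with an estimated correlation). Both lost the call with the block (adjusted p = 0.078 and 0.0513), and in 12 and 11 of 16 alternatives in all. Medians in pairs 1, 2 and 3 were 0.25, 0.856 and 0.125 for skeletal muscle, and 0.245, 0.802 and 1.3 for mesothelium. Adjusted over the list alone, 2 mesothelial genes were higher and 2 were lower, and 0 neural or skeletal muscle genes passed. The remaining 20 of the 35 lists had adjusted p from 0.126 to 0.985. They included the 16 ureteric mesenchyme genes, of which 8 were higher and 8 lower, with Tbx18 lower and Wnt4, a signal of early nephron formation, at 2.89 ± 0.60 (SE; blocked 0.0215). They also included retinoic acid genes, where Rdh10, an enzyme of retinoic acid synthesis, had a change of 1.45 ± 0.25 (SE; blocked 0.031). Canonical WNT targets were not called either, although Sp5, a direct target, was at least 9.37-fold higher (adjusted p = 0.0817, blocked 0.015).

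Controls and nulls 1 and 2 shared a slide, a scan and 20 ng of input RNA, and control and null 3 another slide and scan and 10 ng. With the slide as a block 7 genes passed (5 up, 2 down) and 13 lists, and within the first slide alone 0 genes and 10 lists passed. The second slide held 1 array per group and allows no test of its own. At an unadjusted p under 0.05, 943 genes differed, 546 higher and 397 lower.

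Tbx18VP16 pools differed more widely from control pools, with 1110 of 20388 genes past the threshold, 430 higher and 680 lower, and 1095 of them changed at least 2-fold. The balance of directions depends on the scaling, with 1113 higher and 260 lower when the 75th percentile was taken over all probes, and 561 and 564 with the authors' values. Lists of nephron progenitor and coelomic markers and of p53 targets rose and extracellular matrix genes fell by a test with a preset correlation, whereas with an estimated correlation 0 of these lists passed (adjusted p = 0.241, 0.428, 0.241 and 0.241). Wt1 rose by 2.61 ± 0.30 (SE, n = 2 and 3), the forkhead gene Foxf1 by 2.95 ± 0.45, and the cell cycle inhibitor Cdkn1a by 3.42 ± 0.71. Cdkn1a was well above background on 2 of the 3 control arrays. Lum and Dcn changed by -5.28 ± 0.59 and -3.56 ± 0.32 (SE). The Tbx18VP16 arrays were of another array design and had a slide and scan of their own, so genotype and these technical factors cannot be told apart in this comparison. GFP came from the Tbx18 allele in control pools and from the Hprt locus after Cre in Tbx18VP16 pools. A difference in which cells were sorted thus cannot be told apart from genotype either.

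The largest rises included platelet genes. Pf4, a platelet chemokine, rose by 8.02 ± 1.73 (SE; adjusted p = 0.0389), Ppbp, another, was at least 92.7-fold higher (adjusted p = 0.0143), and Gp9, a platelet membrane glycoprotein, at least 19.2-fold higher (adjusted p = 0.0152). Gjb2, a gap junction gene, was at least 37.3-fold higher, Mettl7b at least 25.1-fold and Tlx1, a homeobox gene needed for spleen formation, at least 13.9-fold (adjusted p = 0.000782, 0.000534 and 0.000574). Adra2a, an adrenergic receptor gene, rose by 5.95 ± 0.35, and Cnr1, a cannabinoid receptor gene, by 5.25 ± 0.29 (SE; adjusted p = 0.000574 and 0.000534). Itga7, a laminin-binding integrin gene, C1qtnf7 and Fhdc1 rose by 5.69, 5.65 and 5.43. Egln3 was at least 27.0-fold higher (adjusted p = 0.000761). Itga7 was well above background on 1 of the 3 control arrays, and Pf4, Adra2a, C1qtnf7 and Fhdc1 on 2. The Fhdc1 value depends on its probe, since without either Tbx18VP16 array another probe stands for the gene and gives -4.95 or -5.04.

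The largest falls included the interferon-inducible gene Ifi204, at -6.71 ± 0.64 (SE; adjusted p = 0.0023), well above background on 1 of the 2 Tbx18VP16 arrays. Its relative Ifi203-ps was at least 21.8-fold lower (adjusted p = 0.00168). Hprt, the housekeeping gene whose locus carried the transgene, changed by -3.98 ± 0.32 (SE; adjusted p = 0.000941). Dkk1, a secreted WNT antagonist gene, changed by -3.79 ± 0.24 (SE; adjusted p = 0.000574). Col25a1, a collagen gene, and Sstr1, a somatostatin receptor, changed by -4.90 and -3.88. Cdh9, a cadherin, and Nts, the neurotensin precursor, changed by -3.78 and -3.77. Sntg1 and Prokr2 were at least 11.2-fold and at least 9.11-fold lower (adjusted p = 0.000872 and 0.0264).

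Of 35 lists, 7 rose and 1 fell, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.241. Targets of p53 rose (camera adjusted p = 7.21e-05, and adjusted p = 0.241 with an estimated correlation), with 13 of 15 measured members higher and 5 passing over all genes, or 7 higher and 1 lower adjusted over the list alone. Pmaip1, which promotes cell death, was at least 18-fold higher (adjusted p = 0.00603), and Phlda3 and Ccng1 rose by 1.47 ± 0.22 and 1.32 ± 0.23 (SE). Nephron progenitor genes rose (adjusted p = 0.000851, and adjusted p = 0.241 with an estimated correlation), with 15 of 18 higher, 3 passing over all genes and 5 adjusted over the list alone. Meox1 rose by 3.90 ± 0.65 (SE; adjusted p = 0.0162). Coelomic and gonadal mesothelium genes rose (adjusted p = 0.000312, and adjusted p = 0.428 with an estimated correlation), with 10 of 11 higher, 2 passing over all genes and 3 adjusted over the list alone. The 2 were Wt1, which the nephron progenitor list also holds, and Amhr2, a receptor of anti-Müllerian hormone, which rose by 3.02 ± 0.57 (SE; adjusted p = 0.0249).

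Ureteric mesenchyme genes rose near the threshold (camera adjusted p = 0.0496, and adjusted p = 0.294 with an estimated correlation; lost in 8 of 11 alternatives, with adjusted p = 0.108 with the replicate block), with 9 of 16 higher and 2 passing over all genes. Adjusted over the list alone, 3 were higher and 1 was lower. The 2 were Foxf1 and Foxf2, forkhead genes of mesenchyme that respond to hedgehog signalling, which rose by 2.95 ± 0.45 and 2.10 ± 0.35 (SE). Chemokine and axon guidance genes rose (adjusted p = 0.00586, adjusted p = 0.279 with an estimated correlation, and 0.0564 without control replicate 1), with 17 of 22 higher, 3 passing over all genes, and 5 higher and 2 lower adjusted over the list alone. Ntn1 rose by 3.31 ± 0.36 and Slit2, another guidance cue gene, by 1.31 ± 0.30 (SE), and Sema3e was at least 4.99-fold higher (adjusted p = 0.0035). Notch pathway genes rose (adjusted p = 0.0434, and adjusted p = 0.428 with an estimated correlation; lost in 6 of 11 alternatives), with 10 of 16 higher, 1 passing over all genes and 4 adjusted over the list alone. This was Jag2, a Notch ligand gene, which rose by 2.77 ± 0.58 (SE; adjusted p = 0.0361) and was well above background on 1 of the 3 control arrays. White blood cell genes rose (adjusted p = 0.000851, and adjusted p = 0.428 with an estimated correlation), with 10 of 13 higher, 1 passing over all genes and 5 adjusted over the list alone. This was the lysozyme gene Lyz2, at least 2.60-fold higher (adjusted p = 0.0486) and well above background on 1 of the 2 Tbx18VP16 arrays.

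Extracellular matrix genes fell (camera adjusted p = 0.0147, and adjusted p = 0.241 with an estimated correlation), with 18 of 23 lower. Over all genes 4 were lower and 1 was higher, and adjusted over the list alone 6 were lower and 1 was higher. Besides Lum and Dcn, Tnc, the tenascin gene, was at least 1.41-fold lower (adjusted p = 0.0116). Eln, the elastin gene, rose by 1.94 ± 0.34 (SE; adjusted p = 0.0184). This list did not pass without control replicate 2 or 3 (adjusted p = 0.088 and 0.13).

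The other 27 lists had adjusted p from 0.103 to 0.988. Erythroid, endothelial and ureteric epithelial genes had medians of -1.07, -0.54 and -0.31 (adjusted p = 0.988, 0.554 and 0.964). In the renal stroma list, whose adjusted p was 0.771, 2 genes were higher and 4 lower over all genes, or 5 and 6 adjusted over the list alone, with Smoc2 at 2.02 ± 0.30 (SE; adjusted p = 0.0119) and Dcn lower. Among canonical WNT targets, where the list's median was 0.36 and its mean -0.04, Sp5 was at least 12.8-fold higher (adjusted p = 0.00636) while Dkk1 and Sfrp1 changed by -3.79 and -0.92. The call of Sfrp1 was lost in 10 of 19 alternatives, and that of Dkk1 in 0. The count of called genes rested on both Tbx18VP16 arrays, with 44 genes without replicate 1 and 37 without replicate 2, and it was 324 without control replicate 2. Of the 1110 genes, 45 were represented by a probe rich in A, a class that varied between arrays.

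**Figure D3:**
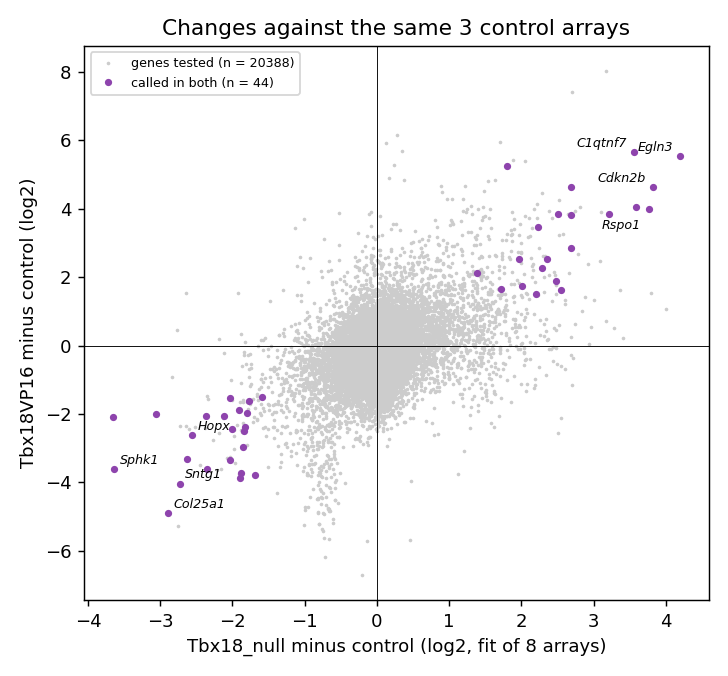
Change of each gene in Tbx18VP16 pools (vertical, log2) against its change in null pools (horizontal, log2), both against the same 3 controls in the fit of 8 arrays, with the 44 genes called in both in purple. All 44 lie in the quadrants of equal sign, 21 higher and 23 lower.

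The direct comparison of Tbx18VP16 with null pools asks where the effects of the activating fusion and of the loss differ. Tbx18 was higher in Tbx18VP16 pools by 3.24 ± 0.46 (SE, n = 2 and 3; adjusted p = 0.0143). Of 20388 genes, 257 were higher and 522 lower in Tbx18VP16 than in null pools, 775 of them at least 2-fold, and the balance turned to 690 higher and 168 lower with the 75th percentile over all probes. Irf5, an interferon regulatory factor, was higher by 4.71 ± 0.25, Npy, the neuropeptide Y gene, by 4.47 ± 0.37, and Adra2a by 4.25 ± 0.35 (SE; adjusted p = 0.000772, 0.00222 and 0.00222). Hoxb1, Dkk1 and Hprt were lower, at -2.92 ± 0.32, -2.97 ± 0.24 and -4.45 ± 0.32 (SE; adjusted p = 0.0062, 0.00222 and 0.00142).

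Gjb2, Mettl7b and Tlx1 were at least 37.0-fold, at least 27.6-fold and at least 15.3-fold higher, and Plppr5 and Tctex1d1 at least 18.2-fold and at least 12.1-fold. Itga7 was higher by 5.34, Corin, a serine protease that activates natriuretic peptide, by 4.57 and Cldn1, a tight junction gene, by 4.17, with Corin well above background on 1 and Itga7 and Cldn1 on 2 of the 3 null arrays. Pabpn1l was at least 9.46-fold higher, on a probe rich in A. Ifi204 was lower by -6.50 and Ifi203-ps at least 19.8-fold, and Ifi204 was well above background on 1 of the 2 Tbx18VP16 arrays. Nts, Sst, the somatostatin gene, Hdc, the histamine-forming enzyme, and Hs3st6 had differences of -4.90, -3.42, -3.33 and -2.97. Cbln4 and Slc17a6, a glutamate transporter gene, were at least 6.05-fold and at least 4.78-fold lower. Genotype, array design and the source of GFP cannot be told apart here either. The count fell to 6 and 0 without Tbx18VP16 replicate 1 and 2, to 165 without null replicate 2 and to 463 without null replicate 3.

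Genes called in both genotypes went the same way. An activating fusion could be asked for changes opposite to those of a loss, but of 44 genes called in both, 21 were higher and 23 lower in both, and 0 went opposite ways. The fit of all 8 arrays called 58 genes in the null, 29 in each direction. Ranked by the lesser of the null and Tbx18VP16 changes, Egln3, Cdkn2b, Rspo1, Sp5, C1qtnf7 and Grhl1, an epithelial transcription factor gene, came first among shared rises. Egln3, Cdkn2b and Sp5 were well above background on no control array, so their rank is uncertain. C1qtnf7 and Grhl1 had changes of 3.56 ± 0.40 and 3.22 ± 0.38 in the null and 5.65 ± 0.44 and 3.84 ± 0.42 in Tbx18VP16 pools (SE). Grhl1 was well above background on 1 of the 3 control arrays. Sphk1, Col25a1, Sntg1, Car3, Hopx and Mrgprx2 came first among shared falls by the same ranking, with Sntg1 at a lower bound in Tbx18VP16 pools. Sphk1 changed by -3.64 ± 0.40 and -3.61 ± 0.45, and Car3, a carbonic anhydrase gene, by -2.63 ± 0.38 and -3.31 ± 0.42 (SE).

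Independent lists of these sizes would share 0.612 higher and 0.967 lower genes, a value that leaves out the shared controls. In 100 simulations of unchanged groups against the same controls there were at most 0 shared calls, but groups without effects yield few calls, so this is no measure of the excess. Of the 175 genes called in the null with the replicate block, 87 were called in Tbx18VP16, 85 in the same direction (43 up, 42 down) and 2 in the opposite, where independence, again without the shared controls, gives 1.92 up and 2.80 down. Across genes, which are not independent replicates, the changes had a correlation of 0.42 and a covariance of 0.172. Simulated unchanged groups gave 0.448 and 0.0771 with independent arrays, and 0.334 and 0.0427 with the deviations that same-numbered pools shared. Of all genes 56.7% had the same sign in both, against 64.8% in the simulation with independent arrays. The share was not computed with the shared deviations. With 3 control arrays no split leaves 2 per side, so part of the excess may come from the shared controls. The count of 44 became 0 without control 2, null 2 or either Tbx18VP16 array, 6 without control 3, 5 without null 3, and 115, of which 3 went opposite ways, without null 1.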

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

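The alternatives that left out probes rich in A or genes of other cell types, those that combined the replicate block with another choice, and the lists on the first slide or with the slide as a block were chosen after the data were seen. The number of arrays, and signal over background for dim probes, limits every value below. Unless stated, the cause of a difference was not tested.

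Null against control gave 0 genes. It gave 12 without a filter, 105 with array weights, 175 with the replicate block, 7 with input RNA or slide as a block, 58 in the fit of all 8 arrays, 1 without A-rich probes and 1 without other-cell genes, and 0 to 3 when 1 array was left out (3 without null 1). The block gave 326 genes without A-rich probes, 197 without other-cell genes, 115 after quantile normalisation, 396 after normexp and 25 without a filter. With the block and 1 pair left out there were 15 genes without pair 1, 0 without pair 2 and 1036 without pair 3. With 1 control and 1 null per number, the block leaves each log2 change as it was, so it could turn no direction. Beyond the calls given in the report it changed none of the list calls.

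Tbx18VP16 against control gave 1110 genes. There were 620 with normexp, 665 with a filter on every array, 3877 with array weights and 37 to 937 with 1 array left out. Against null there were 779, with 396, 449, 5579 and 0 to 674 in the same order. Where 1 Tbx18VP16 array was left out, the other was assumed to vary like the other groups. Tbx18VP16 samples shared only a number with the others, and with the replicate block the counts were 3633 and 3295. With the 75th percentile taken over all probes of each design, the median change of all genes against control moved from -0.14 to 0.31, and the share of higher calls from 38.7% to 81.1% (against null from 33.0% to 80.4%, median -0.15 to 0.29). Quantile normalisation gave 47.5% and 45.8% higher, and the authors' values 49.9% and 49.5%. No named gene reversed under these scalings.

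Genes called in both numbered 44, with 0 in opposite directions, and 1 went opposite ways after quantile normalisation (of 40) and 1 without A-rich probes (of 59). There were 0 with null calls from the 6 arrays, 87 with blocked null calls and 0 to 115 with 1 array left out. Null lists numbered 15, with 1 under an estimated correlation and 0 with the block and an estimated correlation. With 1 array left out there were 9 to 15 (9 without null 3). The fry test called 4 lists, with 3 of the 15 among them, and 7 with the replicate block, with 4 of the 15 among them. Retinoic acid genes, not among the 15, passed fry without and with the block (adjusted p = 0.0245 and 0.0408). Tbx18VP16 lists numbered 8 (7 up, 1 down), with 0 under an estimated correlation, 6 with fry (2 up, 4 down, with 3 of the 8 among them) and 5 to 11 with 1 array left out (5 without control 3).

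Among single genes, normexp reversed the Tbx18VP16 changes of Ntn4 to -0.18 and Upk1b to -0.038, neither of which was called. Fhdc1 reversed to -4.95 and -5.04 without Tbx18VP16 replicate 1 or 2, because another probe then represented the gene, and ranged from -5.04 to 5.59 with 1 array left out. For Tbx18VP16 against control, 116 of the planned gene values lost their call, 55 gained it and 905 kept their side. Against null 40 lost it and 357 kept it. For null against control 95 gained a call and 1127 kept their side, and 0 reversed.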

Other observations

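The Hoxb and platelet gene sets, the rule for A-rich probes and its tests by range, the tests of other cells in the pools and of nephron progenitors, the count of opposite calls, and the covariance with level and base composition taken out were chosen after the results were seen. The tests of other probes of the same genes, of shared controls, of the same other cells in both genotypes and of other splits were written before their results.

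Genes of the Hoxb cluster, homeobox genes that pattern the body axis, had changes above 0 in both genotypes for 9 of 9 measured members, most of them not called without the block. The set was put together after its values were seen and has no enrichment test, and the list of posterior Hox genes fixed beforehand was not called (adjusted p = 0.508 in the null and 0.174 in Tbx18VP16 pools). In the null, in the fit of the 6 arrays, 0 passed without and 5 with the replicate block: Hoxb1, Hoxb2, Hoxb4, Hoxb5 and Hoxb6, at 4.0, 1.96, 1.21, 1.13 and 1.02. In Tbx18VP16 pools 3 passed, Hoxb2, Hoxb4 and Hoxb8, at 2.53, 1.84 and 1.84, whereas Hoxb1 had a change of 1.07 ± 0.32 (SE; adjusted p = 0.094).

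Genes of megakaryocytes and platelets were higher in Tbx18VP16 pools, where 9 of 9 passed. The set was put together after the calls were seen and has no enrichment test, so this count is no evidence of its own. A probe could also meet the filter through the 2 Tbx18VP16 arrays alone. Besides Pf4, Ppbp and Gp9 these were Gp1ba, Gp5, Gp6, Itga2b, Treml1 and Alox12, with changes of 4.48, 3.68, 3.31, 2.68, 4.83 and 4.09. Control levels of Gp1ba, Gp5 and Gp6 lay from -8.45 to -7.3, as low as those of Gp9, whose fold is a lower bound. The size of these changes is therefore uncertain. Levels also differed between null pools: Pf4 was at -6.45, -1.60 and 0.42 in null 1, 2 and 3, against -7.17, -4.74 and -5.24 in controls 1, 2 and 3, and 1.83 and 2.78 in the Tbx18VP16 pools. In the null 2 of these genes were tested and 0 passed.

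Signals of some A-rich probes differed widely between arrays, and 201 such probes had mean levels from -5.69 to -0.19. A first test put the bound for a dependence on probe sequence at a median excess in range of 0.5, and the value missed it: 0.42 over level-matched probes, with 0.70 for C-rich probes. A second test, added after that miss and so weaker as evidence, counted probes that ranged over more than 4 log2, which were 19.1% of A-rich probes and at most 1.89% of any other class. Expression of the probed genes was argued against only for 35 pairs from these 201 probes, which were picked for their wide range: another probe of the gene followed the A-rich probe with a median correlation of -0.114. A dependence on sequence in part of these probes may therefore remain, and no other biological explanation was tested.

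The 54 blood, endothelial and epithelial genes differed between pairs of null and control pools. A loss of Tbx18 that acted alike in every pool was argued against by a median change of 0.106 in pair 1, while other cells in some sorted pools may account for the 3.24 in pair 3, where the next pair had 0.766. The sort on GFP would be meant to remove such cells, and pair 3 was also the pair with 10 ng of RNA on a slide of its own, which stays open. The same other cells as the whole cause of the nephron progenitor rise were argued against by a median change of 0.671 in pair 1. The bound was set after the values were seen, and pair 1 holds 1 array per group. Medians of 1.11 and 1.14 in pairs 2 and 3 leave open a part of such cells for the nephron progenitor genes. For those genes an effect of genotype is a hypothesis, with a change in the mix of GFP-positive cells also open and untested.

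Genes called in both the null and Tbx18VP16 pools had equal signs, whereas over all genes 56.7% had, against 64.8% in the simulation with independent arrays. Shared controls as the whole cause were argued against by a covariance of at least 0.0577 in each of the 3 pairings that shared no control (0.0577, 0.141 and 0.193, without A-rich probes). The array design of the Tbx18VP16 arrays as the whole cause was argued against by a covariance of at least 0.0585 in these pairings after level and base composition of the probes were taken out, while the 0% opposite calls among the 44 restate the pattern. The same other cells in both genotypes stay open too: the covariance of pair 1 was 0.299 of the highest without A-rich probes, between the bounds set for either outcome, but 0.191 over all genes, past the bound set for such cells (0.308 without the other-cell list genes as well). In Tbx18VP16 pools erythroid, endothelial and ureteric epithelial genes had medians of -1.07, -0.54 and -0.31 and were not called. White blood cell genes had a median of 2.11 there, over 13 genes, and the 9 platelet genes were higher. Mean levels of these 13 genes were -3.72 and -3.02 in Tbx18VP16 pools and -5.32, -4.31 and -2.86 in null 1, 2 and 3. In controls 1, 2 and 3 they were -5.13, -5.38 and -5.41, so null 3 stood as high as the Tbx18VP16 pools. All 9 platelet genes were also higher in null 2 and 3 than in controls 2 and 3.

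The 6 control and null arrays make 10 splits, too few for a share under 0.05. The real split called 0 genes and the highest other 4, so that 10 of 10 gave as many. That other split set control 1, null 1 and control 3 against the rest, and so parted control 3 from null 3. It had 4783 genes at an unadjusted p under 0.05, against 943 for the real one. Splits that kept control 1 and null 1 together had 1258 to 4783 such genes. These values point to a difference of control 1 and null 1 from the other pools, and not to a pairing of control 3 with null 3. With the block, 4 splits part all 3 pairs, also too few, and 1 of them, the real one with 175 genes, gave as many, with 0 as the highest other. For gene lists 1 of 10 splits, the real one with 15, gave as many, and the highest other gave 13.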
